A study of Mus musculus with 10 samples.

How the data were processed

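Libraries of poly(A)-selected RNA from whole olfactory epithelium were sequenced as paired-end reads on an Illumina NovaSeq instrument, per the labels' protocols. Genotype is the only difference between the samples in the labels, which give 4 Apoe3 and 6 Apoe4 biological replicates at 6 months. The submitters' processing notes name STAR, featureCounts and DESeq2 and the genome build GRCm38; versions, settings, strandedness and gene annotation are not given in the sources used here.

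The authors deposited 1 table of results per gene, without values per library. Its mean column is a signal averaged over all 10 libraries by the authors, and holds normalized counts, read counts divided by a size factor. The authors' log2 fold changes and their log2 standard errors were shrunk towards 0, as shown by a ceiling of 0.105 on the standard error. The score deposited beside them is the Wald statistic, which equals the log2 fold change divided by its error within 1.3e-13. Each deposited p-value equals the two-sided normal p of that score within 2.8e-15. The authors marked 8314 genes as low, with means up to 9.99, and the adjusted p-values deposited equal Benjamini-Hochberg values over the 16050 other genes with a p-value, within 1.5e-14. Of 24421 genes, 3542 had a mean of 0, and 57 genes with a mean above 10 had no p-value.

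The table does not name the direction of its folds. A gene with 1 read in 1 library has a mean set by that library's size factor alone, and such means took 10 levels, 6 with positive and 4 with negative folds. With 6 Apoe4 and 4 Apoe3 libraries, a positive fold is therefore higher in Apoe4. On simulated data with a known direction, 100% of 404 single-read genes took the sign of their library's group, an outcome that follows from such a fit. The step from 6 positive and 4 negative levels to the direction of the folds was not simulated. The same levels gave the size factor of each library, with a mean of 1.00 in Apoe3 and 1.01 in Apoe4, and with the sum of all means, about 17400000, an approximate depth per library. They do not show which numbered replicate a library is. Means formed 1 level where they were equal after rounding, and each level needed at least 10 genes.

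The design fixed before the data were examined called for a count test, and for the authors' own folds and adjusted p where no values per library were at hand. The second case applied, so all tests of single genes are the authors', at an adjusted p under 0.05. The exact permutation test planned for Apoe over libraries could not be run. Gene lists were tested with cameraPR of limma 3.58.1 (R 4.3.3) on the deposited Wald statistic, two-sided, with a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over lists. Of 56 lists written before the data were examined, 51 had at least 5 tested members. An estimated correlation needs values per library, so a correlation of 0.05 was used beside the preset one; at that value the ribosomal protein, erythroid, oxidative phosphorylation and NRF2 lists still passed, and the other 3 did not.

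Named genes followed a rule fixed in advance: Apoe; the 12 higher and 12 lower genes with the smallest adjusted p among those past the threshold with an absolute log2 fold change of at least 0.3 and a symbol that is not a predicted gene; up to 4 members with the smallest p of each list described; and 8 textbook markers. Some genes that this rule names are not reported here. Xist was named after its value was seen. Symbols were matched to the RefSeq annotation of GRCm38.p6 for positions, 15357 of the tested genes by symbol and 652 by a synonym, and to GENCODE vM21 transcripts for length and GC content, using the longest transcript of each gene. A length was found for 99.4% of tested genes. Where genes overlap or have near-identical copies, as odorant receptors, ribosomal proteins and their pseudogenes, and X and Y homologues do, the authors' counting could have split or dropped reads.

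The length trend was a lowess curve (fraction 0.3) of the Wald statistic on log2 transcript length, and was subtracted as an alternative. This single curve took no account of mean count. Lists were also set against 10000 random lists matched on transcript length, or on length and mean count. Positions of changed autosomal genes were set against 2000 random placements among tested genes, in windows of 2.5 Mb on each side. Shares were compared with Fisher's exact test, two-sided, with 95% intervals of the odds ratio. Shrunken folds understate large changes of low genes, and approximate unshrunken folds were derived from the ratio of each standard error to its ceiling. The test against a fold of 1.2 used the shrunken folds and their errors. Tests were run on simulated counts of 4 against 6 libraries: 10% of genes changed by a fold of 1.2 were recovered, 70% at 1.5, 98.0% at 2 and 100% at 4, and 6 unchanged genes of 16149 tested were called. The median error of unshrunken log2 folds there was 0.064 for true folds of 2 or more. These simulated counts were fitted with their true spread and size factors and held no length trend. They therefore do not show how well the deposited calls are calibrated. A planted list was called, and 0 of 50 random lists. Alternatives were no filter on the mean, a mean of at least 50, and a test against a fold of 1.2, all planned; those added later were removal of the length trend, of X and Y genes and of each list's strongest member, division of the statistic by its spread, ranks, and the higher correlation. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.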

Results

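Poly(A)-selected RNA of mouse olfactory epithelium was sequenced from 10 animals of the C57BL/6 background at an age of 6 months. Olfactory epithelium is the sensory tissue of the nose, in which olfactory sensory neurons lie among sustentacular (supporting) cells, glands and basal stem cells. Of the 10 libraries, 4 came from mice labelled Apoe3 and 6 from mice labelled Apoe4, 2 human alleles of the gene for apolipoprotein E, a lipid carrier. The comparison asks which transcripts differ between the alleles in this tissue. Library sizes were read from genes with a single read in 1 library, and ranged from about 14900000 to 20100000 assigned reads. Size factors ran from 0.859 to 1.14 in Apoe3 and from 0.891 to 1.16 in Apoe4, so depth overlapped between the groups. The highest mean normalized counts in the authors' deposited table belonged to Bpifa1, a secreted airway protein (254337), Cyp2a5, a detoxifying enzyme of supporting cells (164161), and Omp, the olfactory marker protein of mature neurons (113676).

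The largest autosomal change between Apoe4 and Apoe3 was the fall of Wdfy1, which codes for an endosomal protein of Toll-like receptor signalling. Among genes that rose were Serpina3n, a secreted protease inhibitor induced in inflammation, Asns, which makes asparagine, and Eps8l1, a regulator of the actin cytoskeleton. In all, 125 of 16050 genes tested changed at an adjusted p under 0.05 in the authors' deposited table, 52 higher and 73 lower in Apoe4. Most of these changes were small on the shrunken scale, and 22 genes passed when the shrunken folds were tested against a fold of 1.2. Shrinkage contributes to this, since simulated genes with a true log2 fold change of 1 had a shrunken median of 0.69. Simulated data with the same group sizes returned 10% of genes changed by a fold of 1.2 and 70% of those changed by 1.5, so most changes of about 1.2-fold would be missed in such a comparison.

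The mouse Apoe gene (chromosome 7, 19696244 to 19701310, GRCm38, protein coding) was the one that the labels mark as different. In the authors' deposited table its mean normalized count was 249, with a log2 fold change of -0.16 and a standard error of 0.10 (adjusted p = 0.579). Reads of a human allele need not align to the mouse gene, so this value does not measure how much of each allele was transcribed. Values per library were not used here, so the gene could not be checked in every library.

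Wdfy1 (chromosome 1, 79702262 to 79776143) had a log2 fold change of -2.26 with a standard error of 0.06 in the authors' deposited table (adjusted p = 4.8e-294), and its level fell by 79.2%. Serpina3n (chromosome 12, 104406646 to 104414334) rose 2.82-fold, at a log2 fold change of 1.50 with a standard error of 0.07 in the authors' deposited table (adjusted p = 1.2e-91). The authors' deposited table gave Asns (chromosome 6, 7675165 to 7693209) a log2 fold change of 1.16 with a standard error of 0.07 (adjusted p = 9.1e-59). For Eps8l1 (chromosome 7, 4460638 to 4480487) the log2 fold change in the authors' deposited table was 1.14 with a standard error of 0.09 (adjusted p = 2.7e-36). These folds were shrunk towards 0 by the authors' model, and undoing the shrinkage approximately gave -2.50 for Wdfy1, 1.73 for Serpina3n, 1.33 for Asns and 1.46 for Eps8l1.

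Smaller changes went both ways. In the authors' deposited table Col22a1, a collagen of tissue junctions, rose by 0.70 on the log2 scale (adjusted p = 3.7e-09), and Npnt, an integrin ligand of basement membranes, by 0.46 (adjusted p = 2.2e-08). Lower genes included Nnt, the mitochondrial transhydrogenase, of which the C57BL/6J substrain carries a deletion, at -0.65 in the authors' deposited table (adjusted p = 7.9e-09). Dmkn, a secreted protein of epithelia, stood at -0.67 (adjusted p = 2.4e-08) and Alkbh6, of the AlkB demethylase family, at -0.79 (adjusted p = 5.3e-13) in the authors' deposited table. Pcyox1, which breaks down prenylated cysteines, fell by 0.48 (adjusted p = 2.8e-09), Cml5 by 0.65 (adjusted p = 7.2e-08) and Csrnp3 by 0.59 (adjusted p = 8.6e-08) on the log2 scale of the authors' deposited table. With their shrunken folds Kdm5c, Olfr44, Npnt, Olfr1295, Pcyox1 and Csrnp3 did not pass against a fold of 1.2. This does not show that their unshrunken changes were smaller than that.

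**Figure D1:**
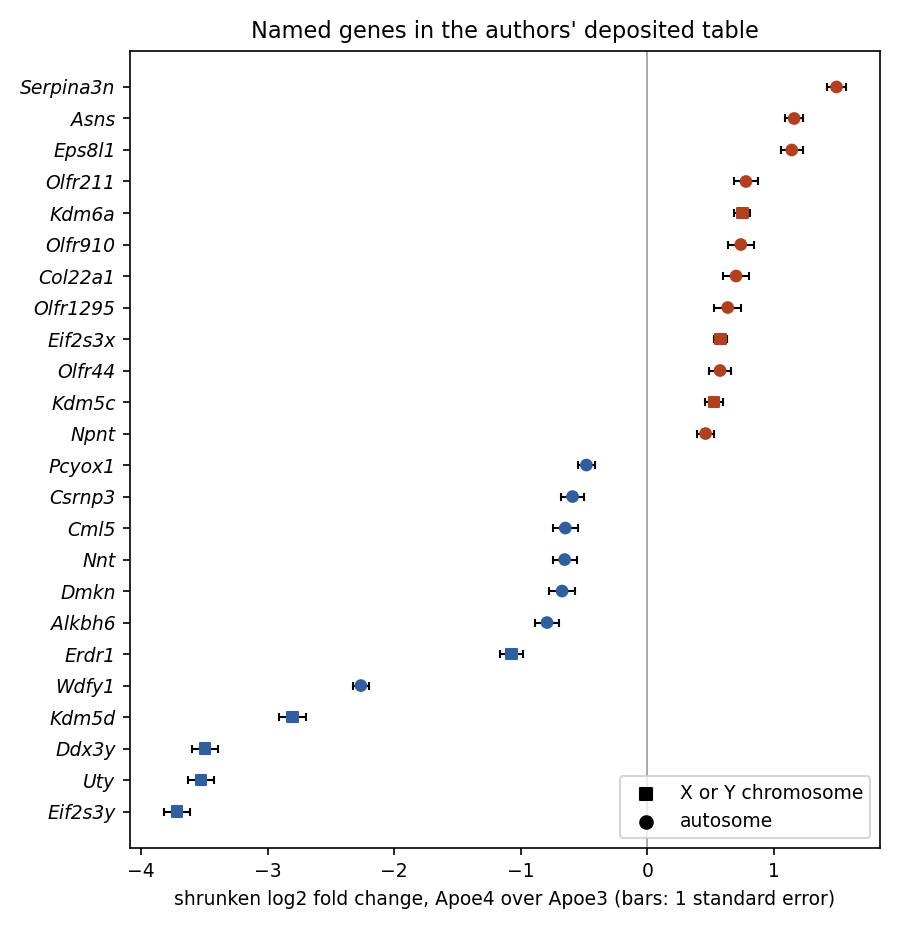
Shrunken log2 fold change of Apoe4 over Apoe3 in the authors' deposited table for 12 higher and 12 lower genes, with bars of 1 standard error. These had the smallest adjusted p among genes with an absolute log2 fold change of at least 0.3, predicted genes left out. Squares are genes of the X or Y chromosome and circles autosomal genes. Serpina3n stands highest at 1.50, Wdfy1 is the lowest autosomal gene at -2.26, and the 4 Y-linked genes lie lowest, down to -3.72.

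Genes of the sex chromosomes separated the groups. All 4 Y-linked genes tested were lower in Apoe4: the authors' deposited table gave log2 fold changes of -3.72 for Eif2s3y (adjusted p = 5.3e-282), -3.53 for Uty (adjusted p = 1.2e-253), -3.50 for Ddx3y (adjusted p = 1.3e-243) and -2.80 for Kdm5d (adjusted p = 1.4e-152). Xist, the long noncoding RNA that silences one X chromosome in female cells (chromosome X, 103460373 to 103483233), had a log2 fold change of 6.41 with a standard error of 0.09 in the authors' deposited table, where it carried no p-value. Genes of the X chromosome that escape this silencing rose, with log2 fold changes in the authors' deposited table of 0.75 for Kdm6a (adjusted p = 3.4e-28), 0.58 for Eif2s3x (adjusted p = 1.1e-23) and 0.53 for Kdm5c (adjusted p = 3.9e-10). Erdr1 fell by 1.07 on the log2 scale of the authors' deposited table (adjusted p = 5.3e-30). The labels give no sex, and every autosomal change reported here ran alongside this sex-linked difference. Of the 125 changed genes, 8 lay on the X and 4 on the Y chromosome, and 113 on autosomes.

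Of 51 gene lists fixed before the data were examined and tested with camera, 5 were lower and 2 higher in Apoe4 as groups. Lower were the lists of ribosomal proteins, erythroid cells, oxidative phosphorylation, the NRF2 and oxidative stress response, and sustentacular cells. The lists of the unfolded protein response and of heat shock proteins were higher. These shifts were mostly of small steps shared by many members, of which few or none passed the test alone. Across genes, the test statistic rose with transcript length (Spearman rho = 0.415 over 15955 genes, which are not independent replicates), and this held beside each list described here. Of 10 bins of length, the one with the shortest transcripts had a median log2 fold change of -0.08 and the one with the longest 0.06. A list whose members are short, such as the ribosomal proteins, lay at the low end of that trend.

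**Figure D2:**
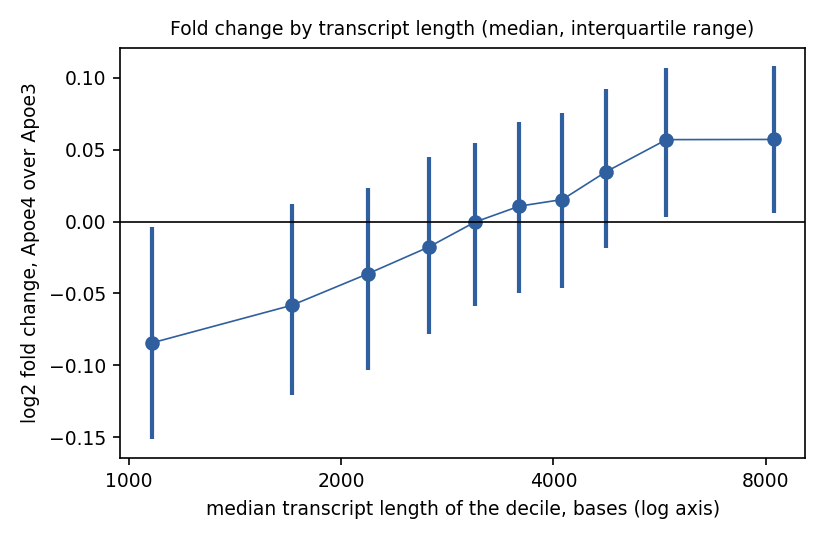
Median and interquartile range of the log2 fold change of Apoe4 over Apoe3 (vertical axis) for tested genes in 10 bins of transcript length (horizontal log axis, bases). The median climbs from -0.08 at a median length of 1076 bases to 0.06 at 8216 bases.

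Ribosomal proteins, the structural parts of the ribosome, were lower as a group (40 members, median log2 fold change -0.18, camera adjusted p = 6.9e-11), and 39 of the 40 had negative values. None of the 40 members changed alone over all genes tested by the authors' DESeq2 test, whereas 12 were lower when adjusted over the list alone and 21 had an unadjusted p under 0.05. Rpl29 and Rps26, ribosomal protein genes outside the list that were picked after their values were seen, were lower alone, both at -0.30 in the authors' deposited table (adjusted p = 0.00677 and 0.0184). Neither passed with the length trend removed (adjusted p = 0.118 and 0.198). The members with the smallest p were Rpl19 at -0.26, Rps25 at -0.23, Rpsa at -0.24 and Rps14 at -0.28 in the authors' deposited table, with adjusted p from 0.174 to 0.229. With the length trend removed the list stayed lower (adjusted p = 6.7e-05). The trend removed was a single curve over all genes. The relation was stronger among genes in the upper part by mean count (Spearman rho = 0.522 over 8013 genes). Removal may therefore have left part of the trend in highly expressed lists such as this one.

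Oxidative phosphorylation genes, which code for the respiratory chain and ATP synthase of mitochondria, were lower as a group (46 members, median log2 fold change -0.16, camera adjusted p = 1.7e-08), with 44 members at negative values. No member changed alone by the authors' DESeq2 test, over all genes or adjusted over the list alone, and 17 had an unadjusted p under 0.05. Uqcrc1 stood at -0.20, Atp5c1 at -0.20, Cox4i1 at -0.25 and Cox5a at -0.23 in the authors' deposited table, with adjusted p from 0.201 to 0.256. With the length trend removed the adjusted p of the list was 0.00175, and 0.0817 with a correlation of 0.05 between genes as well. The limit of a single curve holds here too. Ndufa3, a respiratory chain gene outside the list that was picked after its value was seen, went the other way. It was higher alone, at 0.45 in the authors' deposited table (adjusted p = 4.9e-04), and passed with the length trend removed (adjusted p = 6.4e-06).

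Erythroid markers fell in Apoe4 (10 members, median log2 fold change -0.26, camera adjusted p = 1.7e-09). Of the 10, 4 were lower over all genes tested, and 9 when adjusted over the list alone. Alas2, the first enzyme of haem synthesis in red cells, fell by 0.46 on the log2 scale of the authors' deposited table (adjusted p = 0.00337), and Slc4a1, the red cell anion exchanger, by 0.27 (adjusted p = 0.00509). Car1, a carbonic anhydrase, stood at -0.25 in the authors' deposited table (adjusted p = 0.0171). The members are not short, with a median transcript length of 3454 bases, and the list stayed lower with the length trend removed (adjusted p = 1.7e-10), though Car1 then missed the threshold.

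Genes of the NRF2 and oxidative stress list, which detoxify peroxides and conjugate glutathione, were lower as a group (27 members, median log2 fold change -0.10, camera adjusted p = 1.9e-04). Of the 27, 3 were lower over all genes and 4 when adjusted over the list alone. Gstm1, a glutathione transferase, fell by 0.36 on the log2 scale of the authors' deposited table (adjusted p = 6.6e-05). The glutathione peroxidases Gpx4 and Gpx1 stood at -0.35 and -0.34 in the authors' deposited table (adjusted p = 0.0236 and 0.0351), and both missed the threshold with the length trend removed. Prdx1, a peroxiredoxin, was at -0.20 in the authors' deposited table (adjusted p = 0.157). With the length trend removed the adjusted p of the list was 0.00289, and 0.0805 with a correlation of 0.05 between genes as well.

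Sustentacular cell markers were lower as a group by a smaller step (25 members, median log2 fold change -0.05, camera adjusted p = 0.00648), with 2 members lower over all genes and 3 when adjusted over the list alone. Aldh1a7, an aldehyde dehydrogenase, fell by 0.27 (adjusted p = 0.00172) and Cbr2, a carbonyl reductase, by 0.26 (adjusted p = 0.0421) on the log2 scale of the authors' deposited table. Cbr2 missed the threshold with the length trend removed (adjusted p = 0.309). Cyp2g1, the olfactory cytochrome P450, was at -0.12 in the authors' deposited table (adjusted p = 0.438). Hes1 stood at -0.24 and Krt18 at -0.16 in the authors' deposited table without passing (adjusted p = 0.161 and 0.344). The call was lost at a correlation of 0.05 between genes (adjusted p = 0.105). Of 32 xenobiotic metabolism genes, whose list did not pass (adjusted p = 0.0527), 3 were lower over all genes. The lowest p among them was that of Cyp2e1, at -0.48 in the authors' deposited table (adjusted p = 1.5e-05), and adjusted over the list alone 3 were lower and 1 higher. The xenobiotic list passed as lower with no filter on the mean (adjusted p = 0.0325) and without X and Y genes (adjusted p = 0.0271), but not with the length trend removed (adjusted p = 0.452) or at a correlation of 0.05 (adjusted p = 0.297).

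The unfolded protein response list was higher (24 members, median log2 fold change 0.06, camera adjusted p = 0.0309), with 1 member, Asns, past the threshold over all genes, and 2 higher and 2 lower when adjusted over the list alone. Asns is also induced by amino acid shortage. Without Asns the camera adjusted p of the list was 0.588, and with Asns but on ranks of the statistic it was 0.295. The next members by p were Trib3 at -0.30, Herpud1 at -0.20 and Hsp90b1 at 0.16 in the authors' deposited table, with adjusted p from 0.167 to 0.256. Heat shock and chaperone genes were higher as a group (20 members, median 0.09, camera adjusted p = 0.0366), with no member past the threshold over all genes and 2 higher when adjusted over the list alone (6 at an unadjusted p under 0.05). Hsp90ab1 and Hsp90aa1, the cytosolic HSP90 chaperones, were at 0.17 and 0.21 in the authors' deposited table (adjusted p = 0.174 and 0.201). Hsph1 was at 0.22 and Hspb8 at -0.14 in the authors' deposited table (adjusted p = 0.389 and 0.411). Without Hsp90ab1 the adjusted p of the list was 0.0734, and at a correlation of 0.05 it was 0.207 for both lists.

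**Figure D3:**
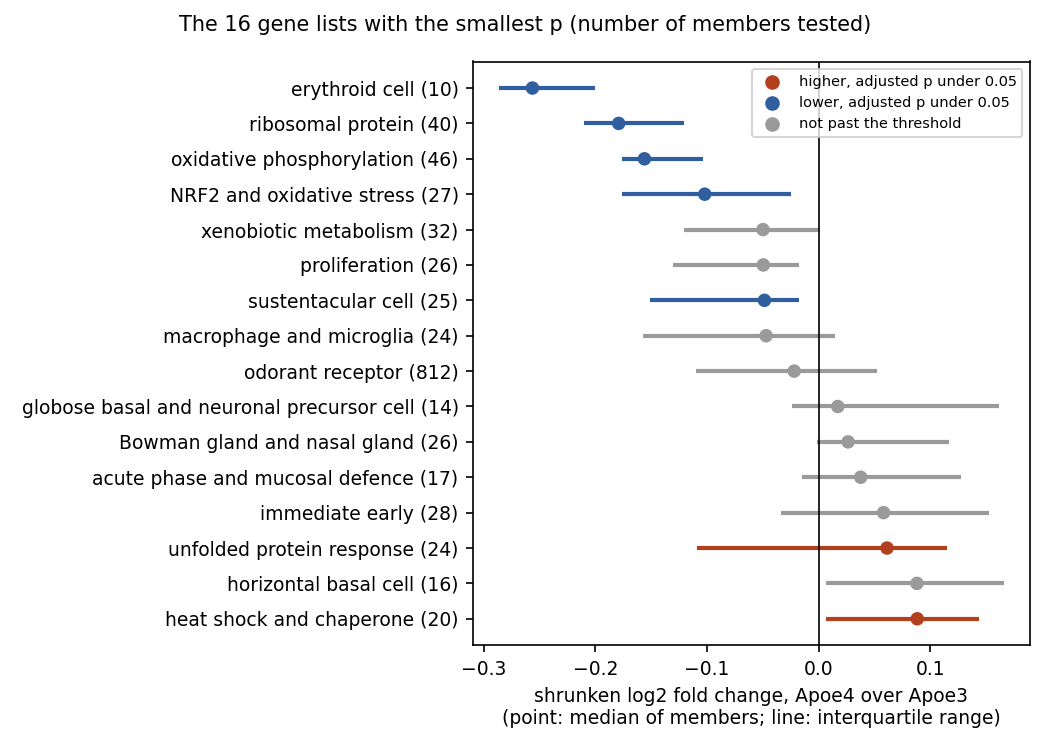
Median (point) and interquartile range (line) of the shrunken log2 fold changes of Apoe4 over Apoe3 among members of the 16 gene lists with the smallest camera p, with the number of members tested in parentheses. Blue lists were lower and red lists higher at an adjusted p under 0.05; the erythroid list has the lowest median, -0.26, and the heat shock list the highest, 0.09.

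Markers of the neuronal lineage did not pass as groups. Mature olfactory sensory neuron markers had a median log2 fold change of -0.05 over 24 members (camera adjusted p = 0.292), and Omp was at -0.06 in the authors' deposited table (adjusted p = 0.828). None of these 24 members changed over all genes or adjusted over the list alone, and 3 had an unadjusted p under 0.05. Calb2 at -0.15, Stoml3 at -0.13 and Slc24a4 at 0.14 in the authors' deposited table had the smallest p, with adjusted p from 0.376 to 0.469. Immature neuron markers had a median of 0.02 over 24 members (adjusted p = 0.556). In that list Dpysl3, a growth cone protein, rose by 0.24 on the log2 scale of the authors' deposited table (adjusted p = 0.0272), 1 higher and 2 lower passed when adjusted over the list alone, and Gap43 was at 0.11 (adjusted p = 0.625). With the length trend removed Dpysl3 missed the threshold (adjusted p = 0.144). Sox4, a transcription factor of neuronal precursors, rose by 0.35 (adjusted p = 3.98e-04) in the authors' deposited table, and was the 1 member of 14 precursor markers to pass, by either adjustment. The precursor list had an adjusted p of 0.136.

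The lists of the other cell types described here did not pass in the main test either, though some did in another setting. Bowman and nasal gland markers had an adjusted p of 0.0734 over 26 members, of which 2 secreted proteins, Bpifb4 at 0.34 (adjusted p = 2.8e-04) and Bpifb1 at 0.43 (adjusted p = 0.0031), rose in the authors' deposited table, by either adjustment. This list passed as higher with the length trend removed (adjusted p = 6.7e-05), with no filter on the mean (adjusted p = 0.0404) and without X and Y genes (adjusted p = 0.0326), but not at a correlation of 0.05 alone (adjusted p = 0.306). Horizontal basal cell markers had a median of 0.09 over 16 members (adjusted p = 0.0734), with Krt5 at 0.14 in the authors' deposited table (adjusted p = 0.576) and no member past the threshold by either adjustment (4 at an unadjusted p under 0.05). The basal cell list passed as higher with no filter (adjusted p = 0.0395) and without X and Y genes (adjusted p = 0.0382), but not with the length trend removed (adjusted p = 0.0774) or at a correlation of 0.05 (adjusted p = 0.297). Macrophage and microglia markers had a median of -0.05 over 24 members (adjusted p = 0.0595). No macrophage marker passed over all genes, 5 had an unadjusted p under 0.05 and 4 were lower when adjusted over the list alone, which included the antigen presentation genes Cd74 and H2-Eb1 at -0.31 and -0.32 in the authors' deposited table (adjusted p = 0.0586 and 0.0692). The macrophage list passed as lower with no filter (adjusted p = 0.0313) and without X and Y genes (adjusted p = 0.0317), but not with the length trend removed (adjusted p = 0.304) or at a correlation of 0.05 (adjusted p = 0.297). C1qa was at -0.07 in the authors' deposited table (adjusted p = 0.837). Microvillar cell markers had an adjusted p of 0.943, with Trpm5 at 0.10 in the authors' deposited table (adjusted p = 0.740). Respiratory multiciliated cell markers had an adjusted p of 0.136, with Foxj1 at 0.10 in the authors' deposited table (adjusted p = 0.699). No microvillar or multiciliated marker passed by either adjustment, and 3 and 5 had an unadjusted p under 0.05.

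Lists close to the function of apolipoprotein E showed no shift past the threshold. Lipoprotein metabolism genes had a median log2 fold change of 0.05 over 27 members (camera adjusted p = 0.577), and none passed over all genes or adjusted over the list alone (3 at an unadjusted p under 0.05). Apod, another lipid carrier, was at -0.20 in the authors' deposited table (adjusted p = 0.417). Cholesterol biosynthesis had an adjusted p of 0.469 over 24 members, with Sqle at 0.12 in the authors' deposited table (adjusted p = 0.469). The complement list had an adjusted p of 0.556, with C4b at 0.25 in the authors' deposited table (adjusted p = 0.291). The disease-associated microglia and interferon response lists had adjusted p of 0.215 and 0.943. In the cholesterol, complement, microglia and interferon lists no member passed by either adjustment, and 1, 1, 2 and 2 had an unadjusted p under 0.05.

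Odorant receptors, the large family of which each sensory neuron expresses a single member, had changed members but did not pass as a list. Of 812 receptors tested, 5 were higher and 12 lower in the authors' deposited table. At 2.09% against 0.709% of other genes they changed more often (odds ratio 3.0, 95% confidence interval 1.67 to 5.05, two-sided Fisher exact p = 1.85e-04). When adjusted over the list alone 7 were higher and 25 lower. The receptors with the smallest p rose: the authors' deposited table gave log2 fold changes of 0.78 for Olfr211 (adjusted p = 2.8e-13), 0.74 for Olfr910 (adjusted p = 1.7e-09), 0.58 for Olfr44 (adjusted p = 2.1e-08) and 0.64 for Olfr1295 (adjusted p = 8.9e-07). The median over all 812 was -0.02 and the list did not pass (camera adjusted p = 0.136). Some receptors are near copies of one another, so reads shared between them could leave single values uncertain, and the genes are not independent of their neighbours.

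Changed autosomal genes lay close together more often than random placement gave. Of the 113, 31 had at least 3 other changed genes within 2.5 Mb, and formed 7 blocks. Chromosome 6 held 17 changed genes among 786 tested (odds ratio 3.09, interval 1.73 to 5.22, adjusted two-sided Fisher exact p = 0.00136 over 21 chromosomes). One of its blocks ran from 7675165 to 8597549 and held Asns with 3 lower genes, and another ran from 85706707 to 86793634 and held Cml5 and Pcyox1. On chromosome 7, blocks ran from 3289038 to 4844866, with Eps8l1 and 4 further genes, and from 28451893 to 30781066, with Alkbh6 and Dmkn among 5. These lie on either side of Apoe: within 20 Mb of it 10 of 395 genes tested had changed (odds ratio 3.78, interval 1.75 to 7.31, two-sided Fisher exact p = 6.3e-04), but within 10 Mb 1 of 227. The windows were chosen after the positions were seen, and neighbouring genes are not independent. Receptor clusters of chromosomes 9 and 11 made up 2 more blocks with 4 receptors each, and 1 block lay on chromosome 2.

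**Figure D4:**
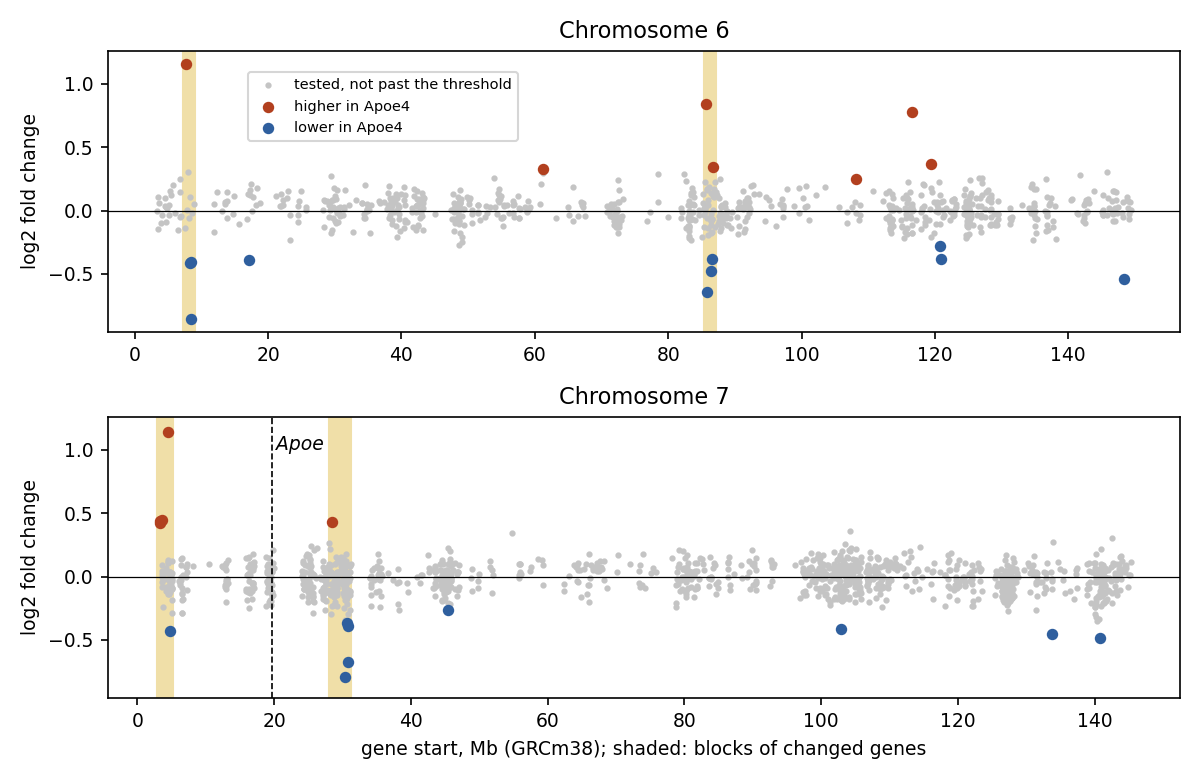
Shrunken log2 fold change of Apoe4 over Apoe3 in the authors' deposited table (vertical axis) against gene start in Mb of GRCm38 (horizontal axis) for genes tested on chromosomes 6 and 7. Coloured points changed, grey points did not pass, shading marks the 4 blocks, which hold 19 changed genes, and the dashed line marks Apoe.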

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

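All tests weighed in this part were chosen after the results were seen. Xist, at a log2 fold change of 6.41, is expressed in the Apoe4 group in the authors' deposited table although no p-value is given for it. A further result was that 57 genes with a mean above 10 had no p-value, 49 of them with positive and 8 with negative folds. Among these were 4 of the 14 measured genes of the olfactory bulb and brain list, Gad1, Slc17a7, Slc32a1 and Grin1, at 28.6% against 0.329% of other genes (odds ratio 120, interval 26.7 to 434, two-sided Fisher exact p = 1.4e-07). One of the 6 Apoe4 libraries held 117 genes with a single read in that library alone, against 32 to 58 in the other 9.

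The Y-linked and Xist differences fit a reading in which the Apoe3 libraries came from males and the Apoe4 libraries from females. The level of Xist in Apoe3 was 1.18% of that in Apoe4, with an upper limit of 1.32%, where 1 female among 4 libraries would give 25%. A single male among the 6 Apoe4 libraries would leave Y-linked genes at 16.7% of the Apoe3 level, and the upper limits ran from 8.76% for Eif2s3y to 16.5% for Kdm5d, so a full male library is argued against, narrowly for Kdm5d and with shrunken folds that overstate the level. Sex and genotype then change together, and for the 113 changed autosomal genes they cannot be told apart, because neither group shows a library of the other sex. An effect of the allele, which the design names, stays open as untested. So do inherited differences between the lines other than the allele, which the blocks of changed genes below also raise.

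The lower ribosomal protein and oxidative phosphorylation lists have short transcripts, and the statistic rose with length. Of 10000 random lists matched on length and mean count, 0% lay as low as the ribosomal proteins. Their mean statistic was -1.86, and the matched lists averaged -1.15, or -0.69 when matched on length alone. The removed curve took no account of mean count, so part of the trend may remain after its removal. The camera call for ribosomal proteins held with the trend removed at either correlation (adjusted p = 6.7e-05 and 0.0258). Random lists do not carry the correlation among ribosomal proteins, which needs values per library, so length and mean count cannot be excluded as the whole cause. For oxidative phosphorylation 0.1% lay as low, but the adjusted p with the trend removed was 0.0817 at a correlation of 0.05, and this part cannot be told apart from the trend without values per library. GC content is argued against as the source of the trend, since the rank correlation with length given GC was 0.404. Differences in RNA integrity or library preparation may underlie the trend and stay open along with allele and sex. The long genes kept as a check of RNA quality showed no rise (23 members, median log2 fold change -0.01, camera adjusted p = 0.822). So few genes cannot decide the question for the trend across all genes.

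Changed autosomal genes lay in blocks: 31 had at least 3 changed genes within 2.5 Mb, against a highest count of 15 in 2000 random placements, so chance is argued against for that number. The most changed neighbours of a single gene, 4, was reached by 11.1% of placements at 2.5 Mb and by 1.2% at 1 Mb. Of the 31, 26 were still called once the length trend was removed, so those calls did not rest on the trend removed. Among all 124 called genes with a transcript length, 87 were. The placement of the genes called without the trend was not set against random placement, so the trend was not tested as a source of the blocks. DNA around Apoe that differs between the lines could account for the chromosome 7 blocks. An example is a stretch carried along from the strain in which each allele was made. The odds ratio within 20 Mb was 3.78, and 1 of 227 genes within 10 Mb had changed. The test cannot tell, because it is not known where such a stretch would lie or end in each line. For the chromosome 6 blocks, which do not lie near Apoe, inherited differences elsewhere and neighbours regulated together were not tested.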

How the results depend on the processing

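Of the alternatives, no filter, a mean of at least 50 and a fold of 1.2 were planned for genes, and all others, those for lists included, were chosen after seeing the data. Against 125 changed genes (52 higher, 73 lower), a fold threshold of 1.2 on the shrunken folds left 22 (10 higher, 12 lower). That is by its construction a stricter question, and shrinkage can make it stricter still for genes with large errors. Dividing the statistic by its spread of 1.21 left 55 (25 higher, 30 lower), by its construction a smaller statistic. The other 4 settings gave 101 to 117, and removing the length trend kept 87 of the calls. Against 7 of 51 gene lists, 4 passed at a correlation of 0.05, 15 with no filter (of 54 lists, the sex check list among the 15), 12 with the length trend removed, 4 with both that and a correlation of 0.05, and 11 without X and Y genes; the cause was not tested. All 7 main calls were among the 15, the 12 and the 11. Ranks of the statistic gave 7, of which 6 were shared. With ranks the unfolded protein response list lost its camera call (adjusted p = 0.295). The proliferation list passed as lower with ranks (adjusted p = 0.0351), though not in the main test (adjusted p = 0.112). Without its strongest member 5 of the 7 lists still passed. Apoe stayed short of the threshold in every setting run. No called list changed its direction. Nor did a called gene covered by the naming rule when the length trend was removed. The other settings for genes kept the deposited sign by construction, so they could not show a change of direction. Of 225 genes covered by the naming rule besides Apoe, many, such as Rpl19 and Omp, were not called in the main test and had no call to lose. The fold threshold of 1.2 ended 23 calls among the 225, and dividing the statistic by its spread ended 12. Removing the length trend ended 7 and added 1, and no filter ended 2.

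No paired analysis was possible because the table has no values per library, although both groups have replicates numbered 1 to 4. For the same reason another count test, other normalizations, leaving out each library, a sex term, a surrogate variable, equal group sizes, fry, an estimated correlation and other splits of the samples were not run, so it is unknown whether 1 library decides a call. Small changes are poorly detected with 4 against 6 libraries, where 10% of simulated changes of 1.2-fold were recovered; depth was not varied.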

Other observations

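The tests in this part were chosen after the data were seen, apart from the lists. With the length trend removed 5 further lists passed, all higher in Apoe4: Bowman and nasal gland (adjusted p = 6.7e-05), acute phase and mucosal defence (0.0112), respiratory multiciliated cell (0.0112), odorant binding and secreted lipocalin (0.0226) and immediate early genes (0.025). In the acute phase list Slpi, a secreted inhibitor of proteases in mucus, rose by 0.47 on the log2 scale of the authors' deposited table (adjusted p = 0.00114). The acute phase list also passed with no filter on the mean (adjusted p = 0.0417). At a correlation of 0.05 beside removal of the trend, the gland list kept its call (adjusted p = 0.0148) and the other 4 did not (adjusted p from 0.0817 to 0.179). Without the trend correction the 5 lists had adjusted p from 0.0734 to 0.666.

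Lymphoid markers were low in this tissue. Of 25 B and plasma cell markers 10 were tested, with a median log2 fold change of -0.09 (camera adjusted p = 0.201), and of 22 T and NK cell markers 9, with a median of -0.07 (adjusted p = 0.250). Both passed as lower with no filter on the mean, which admits more low genes (adjusted p = 0.0325 and 0.0416), but not with the length trend removed (adjusted p = 0.454 and 0.431) or at a correlation of 0.05 (adjusted p = 0.365 and 0.411). The list of long genes kept as a check of RNA quality had a median of -0.01 over 23 members (adjusted p = 0.822).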
